A study of Homo sapiens with 12 samples.

How the data were processed

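Total RNA from HEK293T, an established human embryonic kidney cell line, was measured by stranded, ribosomal RNA depleted sequencing in 12 libraries. Each library came from 1 of 6 single-cell clones that carry a lentiviral construct repressed by doxycycline (DOX). Clones 9, 10 and 12 encode 15 glycines fused to eGFP and an HA tag (15xGly), and clones 5, 8 and 26 encode 99 glycines in the same fusion (99xGly). Each clone was grown for 14 days with 10 ng/mL DOX, which keeps the construct off, and for 14 days without it. This gave 4 groups of 3 libraries.

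Per the file headers and the labels, the authors aligned reads with STAR 2.7.1a to GRCh38 and counted fragments per gene with featureCounts (Subread 1.6.2, pairs counted as 1 fragment, strand option 2, Ensembl release 104). The deposited values are raw counts of fragments per gene for 60605 genes, beside a length column (other unit) that per the file headers gives the exonic bases of each gene. Of these gene identifiers, 60463 matched a name in the reference and 142 did not. Total counts were 93954410 to 120045225 per library, so counting error is small for a gene at 5 CPM (counts scaled to the library total) or more, and the spread between clones limits the comparisons. The constructs' own transcripts are not among the annotated genes and were not analysed here, so the strength of induction was not measured.

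Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on raw counts, with TMM normalization, filterByExpr at its defaults and Benjamini-Hochberg adjusted p under 0.05. Of the 5 comparisons, 3 used 1 fit of the 12 libraries with a term for each clone (the clone block): the change without DOX in the 15xGly clones, the same change in the 99xGly clones, and the difference of these effects. The other 2 compared 3 clones against 3 clones with and without DOX and had no block. The clone block was chosen before the data were examined, because the design text has each clonal line grown both ways. The labels name no test of gene changes and no such block, so the fit without it is given beside the count of genes in each comparison that it changes, and the list calls that it ends are given under the dependence on processing. The numbers bear on the pairing: deviations from the group mean correlated at 0.613 to 0.803 between the libraries of 1 clone, and at -0.57 to 0.0658 between different clones of 1 construct. Deviations sum to 0 within a group, so positive values within clones push those between clones down, and the gap is partly fixed by the calculation. No pair of libraries was near-identical by a chi-square of their counts: the lowest chi-square per degree of freedom was 15.5.

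The named genes followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes at 5 CPM or more that moved the same way in all 3 clones. For the difference of effects, every 99xGly clone had to lie on 1 side of every 15xGly clone. It also took up to 4 called members per list and every tRNA ligase complex member, and the 5 genes with the smallest p where fewer than 5 genes passed. Some of these genes are summarised in the text and not printed.

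The 31 gene lists were also fixed then: tRNA ligase complex, tRNA splicing and end processing, cytosolic tRNA synthetases, unfolded protein response, ATF4 targets (integrated stress response), heat shock response, proteasome, autophagy and lysosome, glycine, serine and one-carbon metabolism, mitochondrially encoded mRNAs, nuclear encoded respiratory chain, mitochondrial ribosome, cytosolic ribosomal proteins, snoRNA host genes, cholesterol synthesis, glycolysis and hypoxia, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, DNA replication, mitosis, NRF2 and oxidative stress, neuronal genes, GGC repeat disease genes with polyglycine partners, extracellular matrix and adhesion, markers of epithelial cells, of fibroblasts and of blood cells, replication-dependent histones, and abundant noncoding RNAs. Each was tested with camera (correlation preset at 0.01), with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. A list member is counted as changed over all genes tested, and separately when adjusted over the list alone.

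The agreement of the induction effects was measured from separate fits of the 6 libraries of each construct, over genes tested in both. The alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of 1 CPM in 3 libraries, removal of mitochondrial and abundant noncoding RNA, glmTreat at 1.5-fold, no block, the libraries of 1 construct alone, limma-voom with duplicateCorrelation, and each clone left out. A correction of each library for gene length and GC content (lowess span 0.3), a term for a set of clones, and the mean of both effects were added after seeing the data. Principal components used log2 CPM with a prior count of 2 over the 2000 most variable genes.

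The tests were also run on simulated data with 200 changed genes. The blocked edgeR fit recovered 88.5% of them for a single construct (65.7% at a log2 change of 0.5) with 3.8% false calls, and 78% for the difference of effects. The fit of 3 against 3 clones recovered 36.5% and 33.5% without and with DOX. There DESeq2 made 44.5% and 43.5% false calls, so its counts in those comparisons carry little weight. For the mean of both effects 10.3% of the edgeR calls were false, above the nominal share. With a length and GC trend added to the simulated libraries without DOX, that comparison called 6923 unchanged genes before the correction and 18 after it. The correction kept 188 of 199 changed genes (94.5%). Their log2 changes were 0.5 to 2 and shared by both constructs, so smaller changes in 1 construct were not tested. Camera called 0 of 20 random lists. The simulated genes were drawn independently, so neither this nor the false-call shares above tested genes that move together. In the 15xGly comparison the correlation estimated within a list was 0.851 for the proteasome, 0.607 for ATF4 targets and 0.257 for histones. It was 0.035 for tRNA synthetases, against the preset 0.01.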

Results

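The libraries ask what 15 or 99 glycines fused to eGFP do to the RNA of HEK293T cells when the construct is switched on by leaving out DOX. Gene counts were read from 12 libraries of 6 clones in 4 groups of 3. Total counts ran from 93954410 in 99xGly clone 5 with DOX to 120045225 in 99xGly clone 26 with DOX. The first principal component held 55.75% of the variance and placed the 4 libraries of clones 12 and 26, which carry different constructs, at 71.56 to 78.16, against -46.57 to -23.37 for the 8 other libraries.

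**Figure D1:**
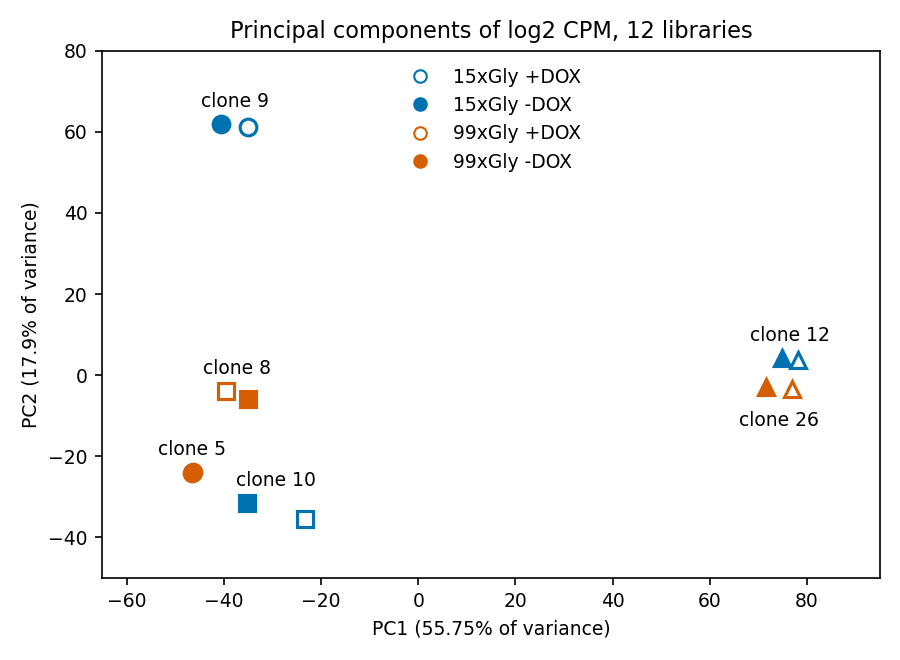
Principal components of log2 CPM for the 12 libraries; each point is 1 library, coloured by construct, open with DOX and filled without DOX, and the axes give the share of variance. The libraries of a clone lie close together, and clones 12 and 26 lie apart from the others on the first axis (55.75% of variance).

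The first comparison asks which genes change when 15xGly is switched on. Without DOX 23 of 44 replication-dependent histone genes, whose products package newly made DNA, and 8 of 34 DNA replication genes rose in the 15xGly clones, while 5 of 22 p53 targets and JUN, a transcription factor of the immediate early class, fell. Camera called these 3 lists, and none held, each at adjusted p = 0.377 with an estimated correlation. Of 25131 genes tested, 769 changed by edgeR with the clone block, 359 higher and 410 lower, and 0 without the block (1537 at unadjusted p under 0.05, against 6625 with it), so each count of list members that rose or fell over all genes in this comparison is 0 without it. The changes were small: the median size was 0.385 on the log2 scale, and 41 of the 769 exceeded 2-fold. ATF5 (ENSG00000169136, chromosome 19, 49928702 to 49933935), a transcription factor of the stress response, rose from 6.92 ± 3.81 to 12.38 ± 4.48 CPM (SD, n = 3), a log2 change of 0.95 (SE 0.168) in 3 of 3 clones. JUN (ENSG00000177606, chromosome 1, 58776845 to 58784048) went from 152.1 ± 43.2 to 92.17 ± 18.1 CPM (SD, n = 3), a log2 change of -0.70 (SE 0.092, adjusted p 0.0173 by edgeR).

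Of 44 replication-dependent histone genes tested, 23 rose over all genes and 34 when adjusted over the list alone, with a median log2 change of 0.31. H4C12 rose by 0.56, H2AC4 by 0.47, H2AC12 by 0.45 and H2BC4 by 0.40. Camera called the list (adjusted p 3e-23), and the call was lost at adjusted p = 0.377 with an estimated correlation. Copies of these genes are near-identical in sequence, so reads may not always be assignable to 1 copy, which was not measured. Of 34 DNA replication genes, 8 rose (24 adjusted over the list alone), among them GINS3 (0.37), TYMS (0.32), UNG (0.30) and CCNE1 (0.29). Of 31 mitosis genes, 3 rose: UBE2C (0.29), CCNA2 (0.26) and KIF23 (0.23). Both lists were called by camera (adjusted p 1.76e-12 and 1.73e-06) and neither held, each at adjusted p = 0.377 with an estimated correlation. In the same clones the change of a gene was correlated with its length across 9950 genes, at Spearman rho -0.375, -0.271 and -0.336 in clones 9, 10 and 12, against -0.12, 0.048 and -0.155 in 99xGly clones 5, 8 and 26. With GC content rho was 0.115, 0.304 and 0.423 in clones 9, 10 and 12, and -0.355, -0.379 and 0.279 in clones 5, 8 and 26. Genes are not independent replicates. No list was tested after a correction for length and GC content.

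Of 22 p53 targets, 5 fell (11 adjusted over the list alone) and 0 rose by edgeR, where 1 member had a positive value. TP53INP1 changed by -0.55, CDKN1A, the inhibitor of cyclin-dependent kinases, by -0.53, ZMAT3 by -0.41 and BTG2 by -0.40. The list median was -0.36 (camera adjusted p 6e-08, and adjusted p = 0.377 with an estimated correlation). Of 30 ATF4 targets, the genes of amino acid supply and stress that ATF4 drives, ATF5 rose while ATF3 (-0.80) and VLDLR (-0.80) fell; 28 of the 30 had negative values, the median was -0.40 and 8 were lower adjusted over the list alone (camera adjusted p 1.73e-06, adjusted p = 0.47 with an estimated correlation). The ATF4 target median was -0.43 in clone 9, -0.50 in clone 10 and -0.05 in clone 12. Of 33 extracellular matrix genes, FN1 (-0.55) and COL9A3 (-0.81) fell; the list median was -0.12 and the estimated correlation gave adjusted p = 0.377.

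Of 33 proteasome genes, PSMC3 (0.31), PSMB4 (0.27) and PSMA4 (0.25) rose and 29 were higher adjusted over the list alone. Of 46 genes of the mitochondrial ribosome 6 rose, led by MRPS17 (0.41) and MRPL1 (0.39), and 30 were higher adjusted over the list alone. Of 71 respiratory chain genes ATP5MC3 (0.32) and NDUFB9 (0.23) rose, with 43 adjusted over the list alone. Of 13 mitochondrially encoded mRNAs, MT-ND2 (0.35) and MT-ND1 (0.25) rose. Of 80 cytosolic ribosomal protein genes RPL24 (0.21) rose, of 19 snoRNA host genes SNHG12 (0.33), and of 21 NRF2 genes GPX1 (0.29). Of 24 genes of tRNA splicing, THG1L (0.47) and POP4 (0.33) rose. Camera called each of these 8 lists higher, and with an estimated correlation each call was lost, at adjusted p = 0.377 for all but the mitochondrially encoded mRNAs and the cytosolic ribosomal proteins, where adjusted p = 0.47.

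The tRNA ligase complex, which joins the exons of tRNAs and of XBP1 mRNA, had 0 of 7 members changed over all genes and 4 higher adjusted over the list alone. RTCB, its catalytic subunit, had a log2 value of 0.21 (SE 0.055, adjusted p 0.0551 by edgeR) and DDX1 0.24 (adjusted p 0.0695). Camera called the list higher (adjusted p 0.00378, adjusted p = 0.377 with an estimated correlation). Of 29 unfolded protein response genes 0 were called by edgeR over all genes and 15 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.377 with an estimated correlation); XBP1, named here after its value was seen, was at -0.18. Of 24 heat shock genes DNAJB4 fell by 0.32 and 14 were higher adjusted over the list alone, with HSPA8, named after its value was seen, at 0.70 (median 0.23, adjusted p = 0.494 with an estimated correlation). STARD4 fell by 0.29 among 24 cholesterol synthesis genes (median 0.16, camera higher, adjusted p = 0.494 with an estimated correlation). JUN was the 1 called member of 21 immediate early genes (median -0.13, adjusted p = 0.377 with an estimated correlation) and NCAM1 (-0.32) of 25 neuronal genes (median -0.17, adjusted p = 0.377 with an estimated correlation).

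Camera did not call the other 11 lists. Of these, FARSB (0.24) rose among tRNA synthetases, TYMS among genes of glycine, serine and one-carbon metabolism, and LMNB1 (0.26), a nuclear lamin, among GGC repeat disease genes and polyglycine partners, where PURA fell by 0.37. PDK1 (-0.34) fell among glycolysis and hypoxia genes. RN7SL1 (0.35) and RNU4-2 (0.62) rose and NEAT1 (-0.57) fell among abundant noncoding RNAs. No member was called by edgeR among autophagy and lysosome genes (median 0.04), interferon-stimulated genes (-0.02), NF-kB and inflammatory genes (0.04), or markers of epithelial cells (-0.01), fibroblasts (-0.19) and blood cells (0.14). Outside the lists, large rises among the named genes were HLF (0.87), PRKAR1B (0.71), LANCL2 (0.69) and PER2 (0.67), the last a gene of the circadian clock, and large falls were GPR50 (-0.94), MIR99AHG (-0.93), LRATD2 (-0.90) and LINC02614 (-0.89).

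The count of 769 depends on the clone block and on which clones were in the fit. Besides the 0 without the block, the count was 2795 with DESeq2, 1233 with limma-voom, 0 with glmTreat at 1.5-fold and 3606 with no filter. It was 236 after a length and GC correction and 16 from the 6 libraries of the construct alone. With a clone left out it was 0, 36 and 2292 without 15xGly clones 9, 10 and 12. It was 8, 562 and 1002 without 99xGly clones 5, 8 and 26. Where the count fell most, many genes kept an unadjusted p under 0.05. These were 4836, 3719 and 5842 without clones 9, 10 and 5, and 5609 from the construct alone, against 6625 in the main fit (1257 by chance). The library of clone 10 with DOX stood apart: its counts differed from those of its own pair by a chi-square per degree of freedom of 149.2, against 15.5 to 61.6 in the pairs of the 5 other clones, and the called genes had a median change of 0.546 in clone 10, against 0.349 in clone 9 and 0.257 in clone 12. For 767 of the called genes the 99xGly clones with DOX stood 0.303 in the direction called from the 15xGly clones with DOX, and without DOX 768 of them stood at -0.027, a contrast that shares libraries with the test that chose the genes.

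**Figure D2:**
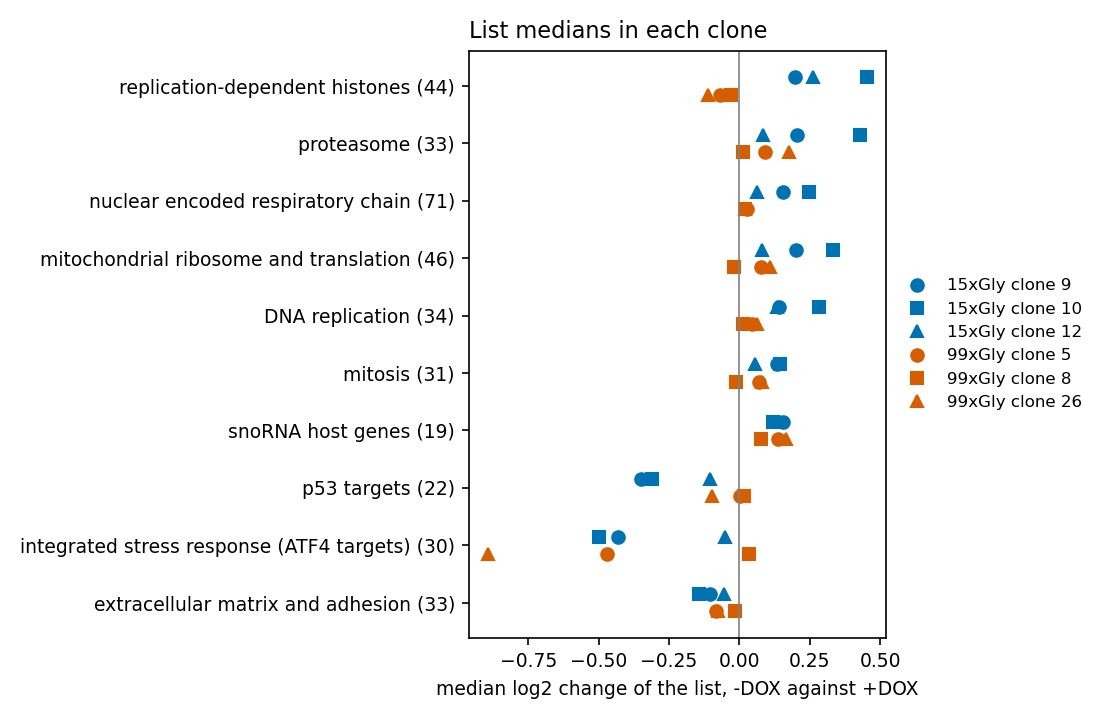
Median log2 change without DOX against with DOX of 10 gene lists (number of genes in brackets) in each clone; each point is 1 clone, blue for 15xGly and orange for 99xGly. The histone medians were 0.196 to 0.452 in the 15xGly clones and -0.112 to -0.029 in the 99xGly clones, and the ATF4 target medians ran from -0.892 in clone 26 to 0.033 in clone 8.

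The second comparison asks the same of 99xGly. ATF4 targets were the list with the largest values: 27 of 30 were lower without DOX, the median log2 change was -0.52, and 20 were lower adjusted over the list alone, though 0 passed over all genes by edgeR. Examples, chosen after their values were seen, are CHAC1 (-1.55), SLC6A9, a glycine transporter (-1.07), VLDLR (-0.96), DDIT4 (-0.95), SESN2 (-0.84), and the serine synthesis enzymes PSAT1 (-0.55) and PHGDH (-0.29). The camera adjusted p was 1.98e-24, and adjusted p = 0.371 with an estimated correlation. Of 19 snoRNA host genes 10 were higher adjusted over the list alone, led by SNHG5 (0.43), ZFAS1 (0.31) and SNHG15 (0.26), with adjusted p = 0.317 with an estimated correlation. Per clone, the ATF4 target median was -0.47 in clone 5, 0.03 in clone 8 and -0.89 in clone 26.

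No gene changed with 99xGly by edgeR (0 of 25131, smallest adjusted p 0.108), with 2498 at unadjusted p under 0.05; DESeq2 called 94 and limma-voom 0. The smallest p belonged to PRSS23 at a log2 value of 0.89 (SE 0.124), EMILIN2 at 0.82 (SE 0.117), VIM at 0.46 (SE 0.065), ANXA1 at 1.58 (SE 0.233) and SNHG5. VIM (ENSG00000026025, chromosome 10, 17228241 to 17237593), an intermediate filament, had 299.7 ± 182.6 CPM with DOX and 397 ± 200.3 CPM without (SD, n = 3) and was higher in 3 of 3 clones. RTCB stood at 0.03 and the tRNA ligase complex list at a median of 0.03. Camera called 13 lists, 8 higher and 5 lower, and 0 held with an estimated correlation (adjusted p 0.317 to 0.637). Fitting the 6 libraries of the construct alone called 27 genes, no filter called 326, leaving out clones 10, 8, 12 and 26 called 48, 19, 2 and 1, and without the block edgeR called 0 (536 at unadjusted p under 0.05).

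**Figure D3:**
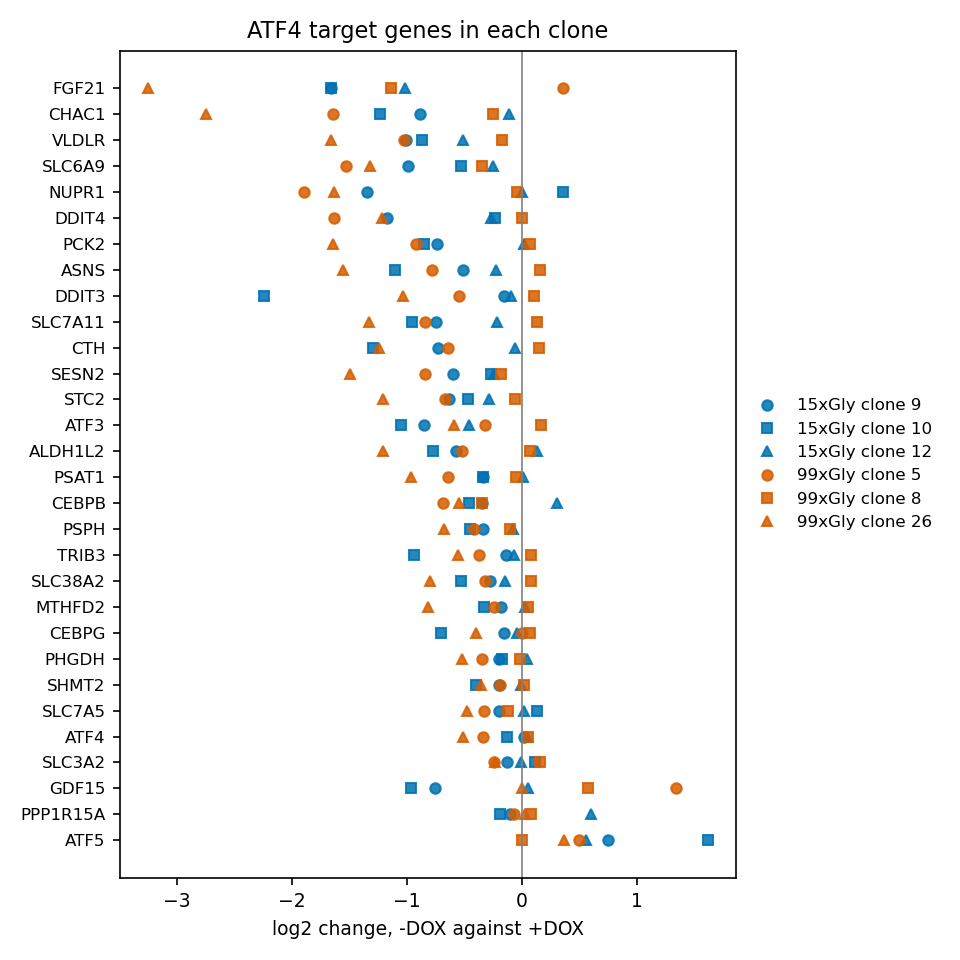
Log2 change without DOX against with DOX of the 30 ATF4 target genes tested; each point is 1 clone, blue for 15xGly and orange for 99xGly. The list median was -0.398 over the 15xGly clones and -0.515 over the 99xGly clones.

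The third comparison asks which genes change differently without DOX between 99xGly and 15xGly. Different clones carry the constructs and the strength of induction was not measured, so repeat length cannot be told apart from these. JUN and H4C12, 1 of 44 replication-dependent histone genes, were among the genes that differed. Of 25131 genes 21 passed, 4 with a higher and 17 with a lower change in the 99xGly clones, and 0 passed without the block (886 at unadjusted p under 0.05, against 3213 with it). The adjusted p of the 21 genes ran from 0.0444 to 0.0498 by edgeR, so each lay close under the threshold of 0.05. JUN differed by 0.89 (SE 0.129): it stood at -0.62, -1.03 and -0.44 in 15xGly clones 9, 10 and 12, and at 0.02, 0.26 and 0.29 in 99xGly clones 5, 8 and 26. CACNB4, a calcium channel subunit, differed by 0.89 (SE 0.120), the zinc transporter SLC39A10 by 0.62 (SE 0.097) and DTNA by 0.61 (SE 0.099). The histone genes H4C14 (-1.03) and H2BC12L (-1.02), which are not among the 44 genes of the list, and H4C12 (-0.87), which is, differed the other way. By type, 8 of the 21 were protein coding, 9 were pseudogenes and 4 were other RNA, the last RN7SK copies. The 9 pseudogenes and 4 RN7SK copies were all lower. The 4 protein coding genes that were lower were H4C14, H2BC12L, H4C12 and ENSG00000203812 (-1.08). Pseudogenes, RN7SK copies and histone genes may share reads with genes of similar sequence, which was not measured. These kinds of gene make up all of the 17 lower genes but ENSG00000203812.

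Among the lists, 19 were called by camera, 16 lower and 3 higher, and 0 held with an estimated correlation (adjusted p 0.53 to 0.695). Of the called lists, replication-dependent histones had the lowest median (-0.38, with 1 of 44 genes lower over all genes and 31 of 44 lower adjusted over the list alone, adjusted p = 0.53 with an estimated correlation), and p53 targets the highest (0.21, 4 of 22 higher adjusted over the list alone, adjusted p = 0.532 with an estimated correlation). RTCB differed by -0.17 (SE 0.078, adjusted p 0.379 by edgeR). DESeq2 called 397 genes, no filter 825, and the 21 fell to 0 with a filter of 1 CPM, with glmTreat, after a length and GC correction, and without clones 9, 5 or 8. Without clones 10, 12 and 26 there were 33, 46 and 99.

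The effects of the constructs were then compared gene by gene, each from its own 6 libraries. Over 22882 genes the across-gene Pearson r was 0.076 and Spearman rho 0.132, and over 11549 genes at 5 CPM or more they were 0.318 and 0.348; genes are not independent replicates. At unadjusted p under 0.05 and in the same direction, 476 genes were higher in both (165.1 by chance, Fisher's exact p 6.37e-114) and 415 lower in both (193.5 by chance, Fisher's exact p 1.52e-56). Fisher's test takes genes as independent units, so these p-values do not measure agreement over clones. The separate fits called 16 genes, all lower, for 15xGly and 27 for 99xGly. Without clone 26 r was -0.064, and without the block 0.087. Between single clones, over genes at 5 CPM or more, clone 26 correlated at 0.487, 0.516 and 0.218 with 15xGly clones 9, 10 and 12. Clone 5 did so at 0.258, 0.19 and 0.092, and clone 8 at -0.202, -0.253 and -0.044.

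The last 2 comparisons set 99xGly clones against 15xGly clones, 3 against 3, without and with DOX. No gene was called in either by edgeR: 0 of 23521 without DOX (1014 at unadjusted p under 0.05) and 0 of 23548 with DOX (995), while limma-voom called 0 and DESeq2 49 and 31. Without DOX, GPC3, a glypican, had a log2 value of -1.23 (SE 0.176), RN7SL4P -0.54 and TNFRSF9 2.30. With DOX, DENND2A stood at -1.40 (SE 0.223), the kinase gene CDK13 at -0.53 (SE 0.096), ZNF331 at 1.40 and PDGFD at 1.90. RTCB stood at -0.25 and -0.06. GPC3 had 33.04 ± 6.63 CPM in the 15xGly clones and 14.06 ± 1.88 CPM in the 99xGly clones without DOX (SD, n = 3).

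Lists called by camera numbered 11 without DOX and 17 with DOX, and 0 held with an estimated correlation (adjusted p 0.172 to 0.819, and 0.409 to 0.611). Mitosis genes had positive values in 29 of 31 without DOX (median 0.15) and 31 of 31 with DOX (median 0.29). Autophagy and lysosome genes had positive values in 33 of 37 without DOX (median 0.12), where fry gave adjusted p 0.00959. This was the only list that fry called in any comparison. Neuronal genes had medians of -0.35 and -0.34. Proteasome (0.17), histone (0.24) and mitochondrially encoded genes (0.24) were at positive medians with DOX, when the constructs are repressed.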

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

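The tests of clone 10, of a change shared by both constructs, of clone 26, of clones left out of the ranking and of a mixture of cells were chosen after the results they measure were seen, and so was the length and GC correction as a setting.

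The effect of leaving out DOX differed between the constructs for 21 genes, in a test of the difference itself (adjusted p 0.0444 to 0.0498 by edgeR). The log2 difference, 99xGly minus 15xGly, was 0.888 for CACNB4, 0.886 for JUN, 0.615 for SLC39A10 and 0.613 for DTNA, and -1.027 for H4C14, -1.018 for H2BC12L and -0.868 for H4C12. The same difference, as a median over a list that camera called, was -0.379 for replication-dependent histones, -0.273 for abundant noncoding RNAs, -0.171 for the tRNA ligase complex, -0.167 for ATF4 targets, -0.158 for tRNA splicing, -0.141 for glycine, serine and one-carbon metabolism, -0.137 for the mitochondrial ribosome, -0.135 for DNA replication, -0.132 for the proteasome and for mitochondrially encoded mRNAs, -0.125 for the unfolded protein response, -0.123 for the respiratory chain, -0.122 for tRNA synthetases, -0.093 for mitosis, -0.085 for NRF2 genes and -0.076 for cytosolic ribosomal proteins. It was 0.211 for p53 targets, 0.134 for immediate early genes and 0.116 for extracellular matrix genes. None of these list calls held with an estimated correlation (adjusted p 0.53 to 0.695). Of the 10 splits of the clones between the constructs, 1 gave 21 genes or more, the real one, and the highest other gave 3. By genes at unadjusted p under 0.05 the split that grouped clones 9, 10 and 26 came close, with 3196 against 3213. That split also gave the 3 called genes, and 10 splits are too few for a share under 0.05.

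The 769 genes changed with 15xGly are the first pattern. Whether clone 10 drives the calls stays open: without it the median change of the called genes was 0.303, against 0.385 with it (78.5%), but these genes were chosen with clone 10 in the fit, the count fell from 769 to 36, and 3 of 10 splits, the real one and a pair that set clone 10 with DOX against clone 10 without it, called as many genes or more (highest other 2514; the other splits that part all 3 pairs called 0, and 10 splits are too few for a share under 0.05). A change on DOX removal shared by both constructs stays open too: the called genes moved by 0.075 in the 99xGly clones (19.4%) and 70.1% of them in the same direction, and in 769 genes ranked without a 15xGly clone the median change was 0.266, 0.432 and 0.159 in left-out clones 9, 10 and 12, against 0.147, 0.117 and 0.193 in 99xGly clone 26, 0.06, 0.07 and 0.118 in clone 5, and -0.029, -0.024 and -0.028 in clone 8. So do gene length and GC content: after the correction 198 of 763 called genes passed (26%), all 763 had the same sign, and the median change over these genes went from 0.384 to 0.318 and the median SE of a single gene from 0.082 to 0.074, with a median adjusted p of 0.0613. The response to 15xGly that the design names stays open beside these.

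The lower level of ATF4 targets without DOX is the second pattern. A change shared by both constructs stays open: 27 of the 28 members lower in the 15xGly clones were also lower in the 99xGly clones (96.4%), but 27 of all 30 members were lower there, which fixes most of that share. The list median was -0.43, -0.499 and -0.053 in 15xGly clones 9, 10 and 12 and -0.47, 0.033 and -0.892 in 99xGly clones 5, 8 and 26, so clones 12 and 8 had almost no fall, and no clone without a construct was measured. Whether clone 26 alone sets the size in the 99xGly clones stays open: without it the list median was -0.246, against -0.515 with it. For the 99xGly comparison, which called 0 genes by edgeR (2498 at unadjusted p under 0.05, DESeq2 94, limma-voom 0), 10 of 10 splits gave as many and the highest other gave 0, so the splits say nothing.

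Clones 12 and 26, from different constructs, stood apart from the other 4 clones. A mixture with another cell line stays open: 1 gene, FAM20C, was at 2 CPM or more in each of the 8 other libraries and under 0.05 CPM in each of these 4, and 9 genes showed the opposite, too few to decide. Shared gains and losses of chromosome segments stay open too: the variance between 481 windows of 25 neighbouring genes was 2.94 times that in shuffled gene order (highest of 1000 shuffles 1.26), but single clones gave 2.68 to 4.01. The rule that this ratio must exceed every clone alone was set after the values were seen. No biological explanation was tested.

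Between the constructs, 3 clones against 3, edgeR called 0 genes without DOX (1014 at unadjusted p under 0.05, DESeq2 49, limma-voom 0) and 0 with DOX (995, DESeq2 31, limma-voom 0). All 10 of 10 splits gave as many in each, with 47 and 43 genes in the highest other, and 10 splits are too few for a share under 0.05.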

How the results depend on the processing

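The length and GC correction was chosen after seeing the data, as were the clone-set term and the mean of both effects. The counts below are genes changed with 15xGly, with 99xGly and differing between these effects, against 769, 0 and 21. With no filter they were 3606, 326 and 825, with DESeq2 2795, 94 and 397, and limma-voom gave 1233 for 15xGly. With a filter of 1 CPM the difference of effects gave 0. With glmTreat and with no clone block, 15xGly and the difference of effects gave 0 each. Without the block, camera lost 4 list calls for 15xGly (mitochondrially encoded mRNAs, immediate early, neuronal and extracellular matrix genes) and 7 for the difference of effects (tRNA ligase complex, ATF4 targets, glycine, serine and one-carbon metabolism, mitochondrially encoded mRNAs, immediate early, NRF2 and extracellular matrix genes). After the length and GC correction the counts for 15xGly and the difference of effects were 236 and 0. Of the named genes for 15xGly, 41 lost their call after this correction and 30 had the same call status. The lists were not tested after it, so whether their calls depend on length and GC content is not known. From the libraries of 1 construct, 16 genes changed with 15xGly and 27 with 99xGly. With each clone left out in turn the counts ran from 0 to 2292, from 0 to 48 and from 0 to 99. The 15xGly count was 0 without clone 9 and 8 without clone 5. For 3 clones against 3, DESeq2 gave 49 genes without DOX and 31 with DOX. The cause of these differences was not tested. By design glmTreat asks for a larger change. Fewer libraries leave fewer degrees of freedom, but this does not account for the counts that rose with a clone left out.

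The Pearson r between the effects of the constructs was 0.076, and -0.064 to 0.189 with a clone left out, the lowest without clone 26. With a clone left out, list medians changed sign for heat shock genes in the difference of effects (-0.194 to 0.07, positive without clone 10 and, at 0.012, without clone 8) and for ATF4 targets in that difference (-0.429 to 0.083, positive without clone 26) and between the constructs with DOX (-0.421 to 0.172, positive without clone 10). The cause was not tested. Of 1911 named-gene values, 20 changed sign where neither value passed, and 0 called genes reversed. DESeq2 gave no adjusted p for 3 values. Depth limits genes under 5 CPM most.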

Other observations

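The mean of both induction effects was added as a comparison after seeing the data, with each of its alternatives, while its tests and that of chromosome 22 were written before their results were seen. Over the 6 clones, 368 genes changed without DOX by edgeR with the clone block, 169 higher and 199 lower, and 0 without the block (1228 at unadjusted p under 0.05, against 5715 with it). RBM3, an RNA-binding protein known for its rise in the cold, rose by 0.32 on the log2 scale, and TIMP1, an inhibitor of metalloproteinases, by 0.51. ONECUT2 (-0.34), IGFBP5 (-0.46), CXCR4 (-0.61), MYB (-0.50), SLC6A9 (-0.83) and VLDLR (-0.88) fell, each in 6 of 6 clones. Of 30 ATF4 targets 8 fell and 1 rose (median -0.44), of 19 snoRNA host genes 4 rose, and of 34 DNA replication genes 4 rose. The count was 0 without clone 9, 0 without clone 5, 0 without clone 26, 1942 without clone 12 and 794 without clone 8, and 4603, 4064 and 3892 genes were at unadjusted p under 0.05 where it was 0 without clones 9, 5 and 26. It was 2812 with no filter, 2165 with DESeq2, 777 with limma-voom, 593 without mitochondrial and abundant noncoding RNA, 228 with a filter of 1 CPM and 0 with glmTreat at 1.5-fold (162 at unadjusted p under 0.05).

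A response to DOX removal, or to either construct, may be common to the 6 clones: 310 of the 368 genes had 1 direction in all 6 clones, though the same test chose them. Over all genes at 5 CPM or more, clone 8 shared little with most clones. Its changes correlated at -0.202, -0.253, -0.044 and -0.012 with clones 9, 10, 12 and 26, and at 0.42 with clone 5. Of the 32 splits that part every clone, 1 called 368 genes or more, the real one, and the highest other called 21. By genes at unadjusted p under 0.05 the split that turned clone 8 alone came close, with 5626 against 5715. The comparison was added after seeing the data, and its count was 0 without clone 9, 5 or 26. The splits therefore do not exclude chance. Of the 368 genes 227 were also called in the 15xGly clones. DOX and the constructs changed together in every clone, so they are confounded.

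Clone 10 had higher RTCB and XBP1 than other clones with and without DOX. A gain of chromosome 22, where both genes lie, may account for it: the median log2 ratio of clone 10 to the other clones was 0.724 over 290 expressed genes of chromosome 22, the highest of all chromosomes, and 0.075 for the next, chromosome 4. The prediction was written before this median was computed. No DNA was measured.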
